A study of Mus musculus with 46 samples.

How the data were processed

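Cells were sorted from bone marrow and spleen with magnetic beads and then by flow cytometry, and libraries were made with the SMART-Seq and Nextera XT kits, per the labels. These libraries are unstranded, so antisense transcripts are not separated. The submitters' processing notes name STAR for alignment to mm10 (GRCm38), Picard, and RSEM for quantification, without versions, and the TPM values were used as deposited by the authors. The table held 20584 genes by symbol for 46 libraries, with 2 biological duplicates in each of 23 groups. The labels do not say whether equal replicate numbers share an animal, so libraries were treated as unpaired. The labels name no batch.

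Genes with at least 1 TPM in at least 2 libraries were fitted, 13750 in all, as log2(TPM + 1) with limma (a mean per group, eBayes with trend, 23 residual degrees of freedom). Tests were two-sided, in 32 contrasts: steps between WT populations, genotypes within a population, KO against d56, and differences of genotype effects between populations. Benjamini-Hochberg adjustment was made within each contrast over genes with a mean of at least 1 TPM in its libraries, and genes with adjusted p below 0.05 were called. With no counts in the table, count models were not run.

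Gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, over lists with at least 3 tested genes. There were 26 lists of 443 symbols, 420 of them in the table. For comparisons between genotypes, signatures of up to 100 genes were added for WT LT-HSC, cDC1, cDC2, Ly6C-Mo and Neu, built from WT libraries that enter no genotype contrast. The list of mitochondrially encoded genes was absent from the table and not tested.

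The tests, lists and the rule for naming genes were chosen before the data were examined. By that rule Irf8 is always given. Other genes come in order of absolute log2 fold change among called genes with at least 10 TPM in the higher group and both libraries of 1 group above both of the other, passing over predicted genes, pseudogenes and antigen receptor segments. From each described list the called genes with the largest fold changes are named. Lists are described in the order of their camera p-value, an order chosen after the data were seen, and so were lists added out of that order. Xcr1, Clec9a, Cd79a, Ddx3y, and Cd74 and S100a9 where single libraries are given, were chosen after their values were seen. So were Car1 in d56 GMP, and Hspa1a, Hspa1b and Jun among the genes shared by the KO populations. Genes near the ceiling have 1 curated RefSeq transcript and a mean TPM over 0.5 of the ceiling, a high percentile of TPM of such genes.

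Correction for transcript length and GC content used GENCODE M21 and covered 97.6% of genes. The correction, the analysis without genes near the ceiling and the comparisons with separate WT libraries for d56 and KO were added after the data were seen. Analyses used R 4.3.3, limma 3.58.1, the data.table package at 1.17.8, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.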

Results

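Gene expression was measured by RNA-seq in 46 libraries from 23 groups of sorted mouse cells of the mononuclear phagocyte lineage and its precursors. There were 14 wild-type (WT) groups. The bone marrow groups were long-term and short-term hematopoietic stem cells (LT-HSC, ST-HSC), the multipotent progenitors MPP2 and MPP3, the Flt3-positive multipotent progenitor LMPP, the granulocyte-monocyte progenitor (GMP), the monocyte-dendritic cell progenitor (MDP), the common monocyte progenitor (cMoP) and the common dendritic cell progenitor (CDP). The spleen groups were classical dendritic cells of types 1 and 2 (cDC1, cDC2), Ly6C+ and Ly6C- monocytes (Ly6C+Mo, Ly6C-Mo) and neutrophils (Neu). A further 5 groups (LMPP, GMP, MDP, cMoP and spleen Ly6C+Mo) came from mice lacking the Irf8 enhancer 56 kb from the gene (d56), and 4 groups (LMPP, GMP, MDP, cMoP) from IRF8-deficient mice (KO). Values were TPM for 20584 genes, so the sequencing depth of each library is unknown. Between 9779 and 12000 genes had at least 1 TPM per library. Replicates correlated at Pearson's r of 0.952 to 0.994 across genes, which are not independent replicates, with d56 Ly6C+Mo the lowest. Levels are mean ± SD with n = 2 libraries per group, fold changes are on the log2(TPM + 1) scale, and adjusted p-values are from limma with Benjamini-Hochberg adjustment. List medians are log2 fold changes, and counts over the list alone, given where they differ, are adjusted over its genes only. Ranges at other settings leave out the leave-one-out fits.

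Irf8 encodes a transcription factor, and its level in each library was examined first. In WT cells Irf8 stood at 11.8 ± 8.78 TPM in LT-HSC, 14.2 ± 8.76 TPM in ST-HSC, 47 ± 12.3 TPM in MPP2 and 364 ± 0.842 TPM in MPP3. It reached 244 ± 122 TPM in LMPP, 183 ± 0.311 TPM in GMP, 888 ± 184 TPM in MDP and 812 ± 118 TPM in cMoP. The highest levels were 1828 ± 254 TPM in CDP and 3028 ± 162 TPM in cDC1, against 502 ± 328 TPM in cDC2, 613 ± 8.23 TPM in Ly6C+Mo, 308 ± 21.1 TPM in Ly6C-Mo and 39.2 ± 6 TPM in Neu. Irf8 has 2 curated RefSeq transcripts.

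In d56 mice Irf8 was 47.2 ± 4.91 TPM in LMPP (log2 fold change -2.26, SE 0.40, adjusted p = 0.00365), 23.6 ± 0.955 TPM in GMP (log2 fold change -2.90, SE 0.40, adjusted p = 0.000196) and 281 ± 21.7 TPM in MDP (log2 fold change -1.64, SE 0.40, adjusted p = 0.0227). It was 405 ± 22.6 TPM in cMoP (log2 fold change -0.99, SE 0.40, adjusted p = 0.133) and 386 ± 63.3 TPM in Ly6C+Mo (log2 fold change -0.67, SE 0.40, adjusted p = 0.192), where the differences did not pass the test. In LMPP the call was lost without WT LMPP replicate 1 (log2 fold change -1.73, adjusted p = 0.158) or without d56 LMPP replicate 1 (-2.15, adjusted p = 0.0799), and with only the compared groups in the fit (adjusted p = 0.154). In MDP it was lost without any 1 of the 4 libraries (-1.85 to -1.43, adjusted p from 0.113 to 0.21) and with quantile normalization (-1.509, adjusted p = 0.146). In cMoP it passed with only the compared groups in the fit (adjusted p = 0.0069). No difference in the Irf8 effect between neighbouring d56 populations passed the test with all groups in the fit, with adjusted p = 1 for GMP against LMPP, MDP against GMP and cMoP against MDP, and 0.701 for Ly6C+Mo against cMoP. With only the compared groups in the fit, MDP against GMP passed (1.26, adjusted p = 0.0499).

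In KO mice Irf8 transcripts were present, at 211 ± 22.9 TPM in LMPP (log2 fold change -0.12, SE 0.40, adjusted p = 0.905), 123 ± 16.4 TPM in GMP (log2 fold change -0.57, SE 0.40, adjusted p = 0.349) and 459.6 ± 8.05 TPM in MDP (log2 fold change -0.93, SE 0.40, adjusted p = 0.0847). The gene fell in KO cMoP, to 228 ± 75.8 TPM (log2 fold change -1.86, SE 0.40, adjusted p = 0.00152). Gene-level TPM sums the whole gene and the labels do not say which part the KO allele lacks, so these levels do not check that label. Against d56, Irf8 was higher in KO LMPP (log2 fold change 2.14, SE 0.40, adjusted p = 0.000751) and KO GMP (log2 fold change 2.33, SE 0.40, adjusted p = 0.00029) and did not pass the test in MDP (adjusted p = 0.287) or cMoP (adjusted p = 0.205). With only the compared groups in the fit, KO against WT passed in GMP (adjusted p = 0.0342) and MDP (adjusted p = 0.00664), and KO against d56 in MDP (adjusted p = 0.0117). In MDP, KO against WT also passed at pseudocount 5 (-0.927, adjusted p = 0.0497), with median-of-ratios scaling (-1.071, adjusted p = 0.0445) and after length and GC correction (-1.099, adjusted p = 0.0366). The KO minus WT difference in LMPP changed sign, to 0.41 with adjusted p = 0.717, without WT LMPP replicate 1. Of the list of Irf8 neighbours on the chromosome, 3 of 10 tested genes fell and 0 rose (5 and 0 over the list alone), with median log2 fold change -0.35, camera adjusted p = 0.034 (0.0496 with estimated correlation) in KO GMP.

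**Figure D1:**
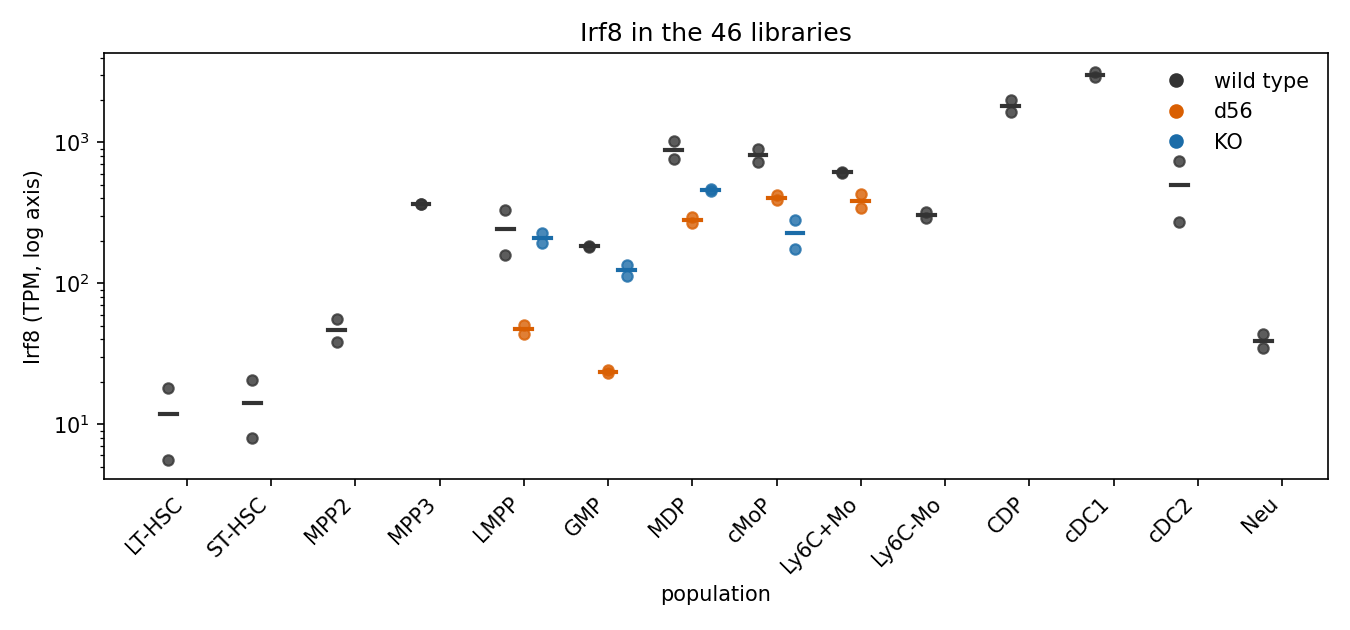
Irf8 in each of the 46 libraries, as TPM on a log axis, by population. Short bars are means of 2 libraries, and d56 GMP averages 23.6 TPM and KO GMP 123 TPM against 183 TPM in WT.

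WT cells were first compared along the lineage. From LT-HSC to LMPP, called genes of the megakaryocyte and stem cell lists fell and those of the lymphoid list rose. Dntt, the template-independent DNA polymerase of early lymphocytes, was listed at 0 in both LT-HSC libraries and at 1615 and 1097 TPM in LMPP, and Treml1, a platelet surface protein gene, fell from 204 ± 5.31 to 0.725 ± 1.02 TPM (log2 fold change -7.03, SE 0.53, adjusted p = 3.84e-11). In the megakaryocyte list, 12 of 12 tested genes fell and 0 rose, first Treml1 and Gp1bb, median -3.48, camera adjusted p = 3.53e-12 (0.00126 with estimated correlation). Within the lymphoid list, 11 of 12 tested genes rose and 0 fell (12 and 0 over the list alone), first Dntt and Satb1, median 2.82, camera adjusted p = 3.56e-10 (0.00126 with estimated correlation). For the stem cell list, 12 of 18 tested genes fell and 0 rose (13 and 0 over the list alone), first Fhl1 and Tek, median -2.24, camera adjusted p = 3.26e-08 (0.00126 with estimated correlation). Irf8 rose (log2 fold change 4.36, SE 0.40, adjusted p = 2.01e-09). It was 3.60 to 5.12 and stayed called on leaving out 1 library. In all 2127 genes were higher and 1912 lower (244 and 1 near the TPM ceiling) of 12092 tested, and 17 of 25 lists were called, 6 with an estimated correlation. The ceiling was 167 to 190 TPM in LT-HSC and 230 to 258 TPM in LMPP, so higher calls near it may follow from it.

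From LMPP to GMP, called genes of the basophil and primary granule lists rose and those of the interferon-stimulated list fell. Prom1, which encodes CD133, rose from 0.57 ± 0.806 to 444 ± 82.6 TPM (log2 fold change 8.23, SE 1.40, adjusted p = 3.49e-05), and Dntt was listed at 0 in both GMP libraries and at 1615 and 1097 TPM in LMPP. Of the basophil, mast cell and eosinophil list, 12 of 15 tested genes rose and 0 fell (13 and 0 over the list alone), first Prg2 and Epx, median 3.9, camera adjusted p = 2.31e-10 (0.00362 with estimated correlation). In the primary granule list, 8 of 11 tested genes rose and 0 fell, first Ms4a3 and Hp, median 1.15, camera adjusted p = 3.96e-09 (0.0101 with estimated correlation). Within the interferon-stimulated list, 24 of 28 tested genes fell and 0 rose, first Ifi27l2a and Ifi44, median -1.94, camera adjusted p = 8.24e-09 (0.0725 with estimated correlation). For the T and NK cell list, 3 of 3 tested genes fell and 0 rose, first Lck and Klrd1, median -3.14, camera adjusted p = 0.0232 (0.182 with estimated correlation). Irf8 did not pass the test (log2 fold change -0.32, SE 0.40, adjusted p = 0.557). It changed sign, to 0.21 with adjusted p = 0.801, without WT LMPP replicate 1, and to 0.059 after length and GC correction. In all 1149 genes were higher and 3433 lower (40 and 32 near the TPM ceiling) of 11546 tested, and 16 of 25 lists were called, 6 with an estimated correlation. Median-of-ratios scaling moved the share of higher calls from 25.1% to 46.4%, and quantile normalization moved it to 51.8%. The 4582 calls became 2891 without WT LMPP replicate 1 and 2913 without WT GMP replicate 2.

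From GMP to MDP, called genes of the monocyte list mostly rose and those of the basophil, mast cell and eosinophil list fell. S100a4, a calcium-binding protein gene, rose from 2.83 ± 1.01 to 56.6 ± 0.29 TPM (log2 fold change 3.94, SE 0.30, adjusted p = 5.39e-10), and S100a9, a calprotectin subunit, fell from 1797 ± 145 to 20.9 ± 19.3 TPM (log2 fold change -6.72, SE 1.30, adjusted p = 0.000665). Of the monocyte list, 12 of 19 tested genes rose and 1 fell (15 and 1 over the list alone), first S100a4 and Klf4, median 1.56, camera adjusted p = 2.18e-19 (0.000357 with estimated correlation). In the basophil, mast cell and eosinophil list, 12 of 15 tested genes fell and 0 rose (15 and 0 over the list alone), first Prss34 and Ms4a2, median -3.34, camera adjusted p = 9.14e-16 (0.000282 with estimated correlation). Irf8 rose (log2 fold change 2.26, SE 0.40, adjusted p = 0.000272). In all 464 genes were higher and 680 lower (19 and 4 near the TPM ceiling) of 10895 tested, and 9 of 24 lists were called, 5 with an estimated correlation. The 1144 calls became 577 without WT GMP replicate 1, 706 without WT MDP replicate 1 and 636 without WT MDP replicate 2.

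In the dendritic cell progenitor CDP, called genes of the pan-DC and pDC lists were higher than in MDP. Cd209a, a C-type lectin of dendritic cells, rose from 2.45 ± 2.66 to 132 ± 24.8 TPM (log2 fold change 5.51, SE 0.58, adjusted p = 3.74e-08), and S100a8, the other calprotectin subunit, fell from 71 ± 6.25 to 0.235 ± 0.332 TPM (log2 fold change -5.89, SE 0.89, adjusted p = 9.19e-06). Within the pan-DC list, 10 of 12 tested genes rose and 0 fell, first Zbtb46 and Itgax, median 1.73, camera adjusted p = 1.73e-07 (0.0437 with estimated correlation). For the pDC list, 10 of 12 tested genes rose and 0 fell, first Siglech and Spib, median 2.24, camera adjusted p = 4.55e-07 (0.0608 with estimated correlation). Irf8 rose (log2 fold change 1.05, SE 0.40, adjusted p = 0.0394), a call lost at pseudocount 0.1 (adjusted p = 0.0546) and without any 1 of the 4 libraries (0.84 to 1.26, adjusted p from 0.0531 to 0.234). In all 1933 genes were higher and 2434 lower (31 and 141 near the TPM ceiling) of 10789 tested, and 14 of 24 lists were called, 2 with an estimated correlation. The 4367 calls became 2743 without WT MDP replicate 2.

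The monocyte progenitor cMoP differed from MDP in few genes. The MDP gate did not use CD135, the Flt3 protein, which the cMoP gate excluded. Cd74, the MHC class II invariant chain, fell from 69.2 ± 16.8 to 2.28 ± 1.75 TPM (log2 fold change -4.51, SE 0.78, adjusted p = 0.00692), and H2-Aa, an MHC class II chain, fell from 16.5 ± 0.905 to 0.83 ± 0.368 TPM (log2 fold change -3.27, SE 0.42, adjusted p = 0.000276). Of the pan-DC list, 2 of 11 tested genes fell and 0 rose (5 and 0 over the list alone), first Flt3 and Id2, median -0.75, camera adjusted p = 8.03e-21 (0.00017 with estimated correlation). In the MHC class II list, 3 of 9 tested genes fell and 0 rose (4 and 0 over the list alone), first Cd74 and H2-Aa, median -0.53, camera adjusted p = 3.68e-15 (0.00378 with estimated correlation). Within the myeloid transcription factor list, 1 of 23 tested genes fell and 0 rose (4 and 0 over the list alone), first Id2, median 0.0, camera adjusted p = 0.00325 (0.0972 with estimated correlation). The mean of that transcription factor list was -0.18. Irf8 did not pass the test (log2 fold change -0.12, SE 0.40, adjusted p = 0.999). It was 0.09 without WT MDP replicate 1 and 0.03 without WT cMoP replicate 2. In all 11 of 22 lists were called, 3 with an estimated correlation. The 11 called lists became 7 without WT MDP replicate 1 and 6 without WT cMoP replicate 2. By limma 0 genes were higher and 8 lower, and 241 had an unadjusted p under 0.05. The 8 calls became 3 without WT MDP replicate 1, 5 without WT MDP replicate 2 and 2 without WT cMoP replicate 2. Called genes numbered 17 with only the compared groups in the fit and 7 to 10 at other settings.

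Against cMoP, CDP had higher called genes of the pan-DC list and lower ones of the late neutrophil list. Cd74 rose from 2.28 ± 1.75 to 1184 ± 729.5 TPM (log2 fold change 8.46, SE 0.78, adjusted p = 3.02e-09), and S100a8 fell from 149 ± 17 to 0.235 ± 0.332 TPM (log2 fold change -6.95, SE 0.89, adjusted p = 7.38e-07). For the pan-DC list, 12 of 12 tested genes rose and 0 fell, first Zbtb46 and Itgax, median 3.0, camera adjusted p = 4.11e-12 (0.0099 with estimated correlation). Of the MHC class II list, 10 of 10 tested genes rose and 0 fell, first Cd74 and H2-Aa, median 2.53, camera adjusted p = 5.45e-10 (0.0295 with estimated correlation). In the late neutrophil list, 11 of 14 tested genes fell and 0 rose, first S100a8 and S100a9, median -3.61, camera adjusted p = 2.22e-06 (0.0645 with estimated correlation). Irf8 rose (log2 fold change 1.17, SE 0.40, adjusted p = 0.0231), lost without WT CDP replicate 1 (1.03, adjusted p = 0.131) or WT cMoP replicate 2 (1.02, adjusted p = 0.142). In all 1860 genes were higher and 2342 lower (40 and 86 near the TPM ceiling) of 10811 tested, and 15 of 24 lists were called, 3 with an estimated correlation. The 4202 calls became 2712 without WT cMoP replicate 2.

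Spleen cDC1 were compared with bone marrow CDP, across tissues. Called genes of the cDC1 list mostly rose and the cell cycle list fell. Cd36, a fatty acid receptor, was listed at 0 in both CDP libraries and at 1770.3 and 1819.9 TPM in cDC1, and F13a1, a coagulation factor chain, fell from 1496 ± 10.8 to 0.015 ± 0.0212 TPM (log2 fold change -10.53, SE 0.69, adjusted p = 6.03e-13). Within the cDC1 list, 16 of 18 tested genes rose and 1 fell, first Cadm1 and Cd8a, median 3.58, camera adjusted p = 1.53e-13 (0.00325 with estimated correlation). For the cell cycle list, 28 of 28 tested genes fell and 0 rose, first Aurka and Foxm1, median -1.61, camera adjusted p = 1.53e-13 (0.00325 with estimated correlation). Of the B cell list, 8 of 9 tested genes rose and 0 fell (8 and 1 over the list alone), first Fcrla and Ms4a1, median 4.3, camera adjusted p = 7.65e-06 (0.0223 with estimated correlation). Irf8 did not pass the test (log2 fold change 0.73, SE 0.40, adjusted p = 0.136). It passed with only the compared groups in the fit (adjusted p = 0.0137). In all 2359 genes were higher and 3159 lower (31 and 156 near the TPM ceiling) of 11230 tested, and 16 of 24 lists were called, 8 with an estimated correlation. Higher genes made up 42.8% of calls, 53.4% with median-of-ratios scaling and 44.1% with quantile normalization.

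Spleen cDC2 had lower called genes of the cell cycle and primary granule lists than CDP. Cd83, a dendritic cell maturation marker, rose from 0.86 ± 1.12 to 817 ± 140 TPM (log2 fold change 8.91, SE 0.67, adjusted p = 1.85e-11), and F13a1 fell from 1496 ± 10.8 to 0.41 ± 0.58 TPM (log2 fold change -10.12, SE 0.69, adjusted p = 2.26e-12). In the cell cycle list, 28 of 28 tested genes fell and 0 rose, first Aurka and Birc5, median -1.62, camera adjusted p = 9.29e-20 (0.000385 with estimated correlation). Within the primary granule list, 8 of 11 tested genes fell and 0 rose, first Mpo and Prtn3, median -3.32, camera adjusted p = 1.03e-08 (0.00929 with estimated correlation). For the cDC2 list, 10 of 16 tested genes rose and 0 fell, first Cd4 and Ltb, median 1.89, camera adjusted p = 0.000365 (0.00929 with estimated correlation). Cd79a, a B cell receptor chain, was 42 and 24.3 TPM in the cDC2 libraries and 0.12 and 0.59 TPM in CDP. Irf8 fell (log2 fold change -2.03, SE 0.40, adjusted p = 0.000167). It stayed called at -2.75 to -1.31 on leaving out 1 library, with 735 and 270 TPM in the cDC2 libraries. In all 3337 genes were higher and 1922 lower (31 and 60 near the TPM ceiling) of 11314 tested, and 16 of 24 lists were called, 6 with an estimated correlation. The share of calls that were higher, 63.5%, became 54.9% with median-of-ratios scaling and 46.2% with quantile normalization.

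Within the spleen, called genes of the cDC1 list were mostly higher in cDC1, and those of the cDC2 and pDC lists higher in cDC2. Hk3, a hexokinase, rose from 1.2 ± 0.219 to 428 ± 16 TPM (log2 fold change 7.61, SE 0.15, adjusted p = 4.41e-24), and Siglech, a lectin of plasmacytoid cells, fell from 1100 ± 534 to 1.88 ± 2.66 TPM (log2 fold change -8.89, SE 0.99, adjusted p = 4.33e-08). Siglech in the cDC2 libraries was 1478 and 722 TPM. Of the cDC1 list, 14 of 18 tested genes rose and 1 fell, first Gcsam and Rab7b, median 2.12, camera adjusted p = 5.47e-17 (0.00126 with estimated correlation). In the cDC2 list, 12 of 16 tested genes fell and 0 rose (13 and 0 over the list alone), first Sirpa and Clec10a, median -2.87, camera adjusted p = 7.34e-08 (0.000502 with estimated correlation). Within the pDC list, 12 of 15 tested genes fell and 0 rose (13 and 0 over the list alone), first Siglech and Klk1, median -2.76, camera adjusted p = 1.14e-07 (0.0568 with estimated correlation). Irf8 was higher in cDC1 (log2 fold change 2.76, SE 0.40, adjusted p = 4.16e-06). The difference stayed called at 2.04 to 3.48 on leaving out 1 library, and whether plasmacytoid transcripts add to Irf8 in cDC2 was not tested. In all 1137 genes were higher and 3078 lower (14 and 70 near the TPM ceiling) of 11473 tested, and 6 of 25 lists were called, 2 with an estimated correlation. Median-of-ratios scaling moved the share of higher calls from 27% to 50%, and quantile normalization moved it to 49.3%.

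From bone marrow cMoP to spleen Ly6C+Mo, the cell cycle list fell and called interferon-stimulated genes rose, across a change of tissue. Cd74 rose from 2.28 ± 1.75 to 6812 ± 672 TPM (log2 fold change 11.13, SE 0.78, adjusted p = 1.33e-12), and Acy1, an aminoacylase, fell from 151 ± 11.8 to 0.045 ± 0.0636 TPM (log2 fold change -7.18, SE 0.28, adjusted p = 1.1e-17). For the cell cycle list, 28 of 28 tested genes fell and 0 rose, first Mcm5 and Ccne2, median -2.95, camera adjusted p = 1.12e-15 (0.00176 with estimated correlation). Of the interferon-stimulated list, 24 of 28 tested genes rose and 0 fell, first Irf7 and Ifit3, median 3.59, camera adjusted p = 1.23e-13 (0.0188 with estimated correlation). In the lysosome list, 15 of 22 tested genes rose and 5 fell, first Cd63 and Lgmn, median 0.77, camera adjusted p = 0.000283 (0.104 with estimated correlation). Irf8 did not pass the test (log2 fold change -0.40, SE 0.40, adjusted p = 0.392). It passed with only the compared groups in the fit (adjusted p = 0.0301). In all 3115 genes were higher and 4277 lower (40 and 178 near the TPM ceiling) of 11044 tested, and 19 of 25 lists were called, 9 with an estimated correlation.

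Between spleen monocyte types, called genes of the Ly6C-negative monocyte list were higher in Ly6C-Mo and those of the monocyte list lower. Mmp12, a macrophage metalloproteinase, rose from 0.535 ± 0.757 to 207 ± 10.6 TPM (log2 fold change 7.18, SE 0.33, adjusted p = 1.4e-15), and Fn1, fibronectin, fell from 9214 ± 1105 to 36.6 ± 7.75 TPM (log2 fold change -7.95, SE 0.83, adjusted p = 3.27e-08). Within the monocyte list, 8 of 22 tested genes fell and 0 rose (9 and 0 over the list alone), first Fn1 and Ly6c2, median -0.62, camera adjusted p = 2.51e-07 (0.0358 with estimated correlation). For the late neutrophil list, 8 of 11 tested genes fell and 1 rose (9 and 1 over the list alone), first S100a8 and Cd177, median -3.55, camera adjusted p = 3.33e-07 (0.0385 with estimated correlation). Of the Ly6C-negative monocyte list, 8 of 17 tested genes rose and 0 fell (11 and 0 over the list alone), first Cd300e and Stap2, median 1.85, camera adjusted p = 3.33e-07 (0.0308 with estimated correlation). Irf8 did not pass the test (log2 fold change -0.99, SE 0.40, adjusted p = 0.0699). It passed at pseudocount 5 (adjusted p = 0.039), with median-of-ratios scaling (-1.07, adjusted p = 0.0478), after length and GC correction (-1.171, adjusted p = 0.0268) and with only the compared groups in the fit (adjusted p = 0.00043). In all 1876 genes were higher and 1023 lower (33 and 18 near the TPM ceiling) of 11031 tested, and 9 of 25 lists were called, 7 with an estimated correlation. Higher genes made up 64.7% of calls, 53.3% with median-of-ratios scaling and 50% with quantile normalization. The 2899 calls became 1916 without WT Ly6C-Mo replicate 1 and 1920 without WT Ly6C-Mo replicate 2.

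From GMP to spleen Neu, called genes of the immediate early list, which handling can induce, and of the interferon-stimulated list mostly rose. Lilr4b, a leukocyte receptor gene, rose from 2.71 ± 0.29 to 5316 ± 1371 TPM (log2 fold change 10.46, SE 0.55, adjusted p = 4.91e-16), and Cox6b2, a cytochrome oxidase subunit, was listed at 0 in both Neu libraries and at 416 and 482 TPM in GMP. In the immediate early list, 16 of 18 tested genes rose and 2 fell, first Nr4a1 and Atf3, median 4.2, camera adjusted p = 7.08e-11 (0.00137 with estimated correlation). Within the interferon-stimulated list, 23 of 27 tested genes rose and 2 fell, first Ifit3 and Ifit3b, median 3.07, camera adjusted p = 4.34e-09 (0.0951 with estimated correlation). Irf8 fell (log2 fold change -2.20, SE 0.40, adjusted p = 1.74e-05). In all 2752 genes were higher and 6415 lower (64 and 119 near the TPM ceiling) of 11209 tested, and 16 of 25 lists were called, 4 with an estimated correlation. The share of calls that were higher, 30%, became 48.5% with median-of-ratios scaling and 47.4% with quantile normalization.

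Populations without the Irf8 enhancer came next. In d56 LMPP, called genes of the cDC1 and tissue macrophage lists were lower. Gria2, a glutamate receptor subunit, rose from 8.78 ± 1.68 to 16.5 ± 3.35 TPM (log2 fold change 0.84, SE 0.14, adjusted p = 0.00143), and Plbd1, a phospholipase-like gene, fell from 40.3 ± 28.8 to 1.53 ± 1.59 TPM (log2 fold change -3.98, SE 0.54, adjusted p = 0.000168). Treml4, a receptor of monocytes and dendritic cells, was listed at 0 in both d56 libraries and at 16.3 and 8.51 TPM in WT. For the cDC1 list, 8 of 16 tested genes fell and 0 rose, first Naaa and Cadm1, median -1.11, camera adjusted p = 6.05e-22 (0.000219 with estimated correlation). Of the tissue macrophage list, 3 of 10 tested genes fell and 0 rose (8 and 0 over the list alone), first Hmox1 and Cd5l, median -1.81, camera adjusted p = 4.55e-16 (1.6e-05 with estimated correlation). In the WT cDC1 signature, 7 of 42 tested genes fell and 0 rose (10 and 1 over the list alone), first Naaa and Cadm1, median -0.4, camera adjusted p = 2.2e-11 (0.0152 with estimated correlation). The 2 WT LMPP libraries differed in genes of these kinds: Xcr1 was 7.16 and 1.26 TPM in replicates 1 and 2, Clec9a 17.6 and 1.88 TPM, and Cd74 1784 and 523 TPM. In all 9 genes were higher and 39 lower (0 and 0 near the TPM ceiling) of 11629 tested, and 14 of 30 lists were called, 4 with an estimated correlation. The 48 calls became 29 without d56 LMPP replicate 1 and 24 without d56 LMPP replicate 2. The calls were 1 with only the compared groups in the fit and 19 to 74 at other settings.

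In d56 GMP, 3 genes of the MHC class II list and 1 of the erythroid list were called lower. Cd300lb, an activating receptor, rose from 9.2 ± 1.98 to 24.5 ± 0.693 TPM (log2 fold change 1.33, SE 0.27, adjusted p = 0.0178), and Cd74 fell from 145 ± 121 to 1.65 ± 1.56 TPM (log2 fold change -5.62, SE 0.78, adjusted p = 0.000196). H2-Aa fell from 23.2 ± 17.3 to 0.34 ± 0.226 TPM (log2 fold change -3.97, SE 0.42, adjusted p = 2.92e-06). Within the MHC class II list, 3 of 10 tested genes fell and 0 rose (5 and 0 over the list alone), first Cd74 and H2-Aa, median -0.61, camera adjusted p = 3.14e-11 (0.0142 with estimated correlation). For the erythroid list, 1 of 12 tested genes fell and 0 rose (3 and 0 over the list alone), first Epor, median -1.27, camera adjusted p = 1.31e-08 (0.0129 with estimated correlation). Of the WT LT-HSC signature, 1 of 81 tested genes fell and 0 rose (5 and 0 over the list alone), first Epor, median -0.2, camera adjusted p = 1.77e-07 (0.0225 with estimated correlation). In all 18 genes were higher and 28 lower (3 and 0 near the TPM ceiling) of 10912 tested, and 8 of 28 lists were called, 5 with an estimated correlation. An unadjusted p under 0.05 was found for 1080. Median-of-ratios scaling moved the share of higher calls from 39.1% to 26.5%, and quantile normalization moved it to 28.6%. Calls were fewer without any 1 library. Called genes numbered 5 with only the compared groups in the fit and 27 to 68 at other settings.

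In d56 MDP, called genes of the interferon-stimulated and lymphoid lists were higher, while of the MHC class II list 2 were called lower and 1 higher. Rtp4, an interferon-stimulated chaperone, rose from 0.28 ± 0.24 to 22.7 ± 4.65 TPM (log2 fold change 4.21, SE 0.26, adjusted p = 2.08e-11), and Cd74 fell from 69.2 ± 16.8 to 6.01 ± 2.76 TPM (log2 fold change -3.36, SE 0.78, adjusted p = 0.016). Aif1, an actin-binding protein of macrophages, fell from 25.9 ± 1.98 to 1.99 ± 0.361 TPM (log2 fold change -3.17, SE 0.51, adjusted p = 0.000558). In the interferon-stimulated list, 9 of 24 tested genes rose and 0 fell (12 and 0 over the list alone), first Rtp4 and Oasl2, median 0.82, camera adjusted p = 1.1e-07 (0.275 with estimated correlation). Within the lymphoid list, 5 of 9 tested genes rose and 0 fell (8 and 0 over the list alone), first Dntt and Vpreb1, median 1.22, camera adjusted p = 2.36e-07 (0.00525 with estimated correlation). For the MHC class II list, 2 of 10 tested genes fell and 1 rose, first Cd74 and H2-Aa, median -0.29, camera adjusted p = 3.94e-05 (0.275 with estimated correlation). In all 228 genes were higher and 53 lower (6 and 0 near the TPM ceiling) of 10823 tested, and 8 of 30 lists were called, 1 with an estimated correlation. Higher genes made up 81.1% of calls, 55.8% with median-of-ratios scaling and 59.3% with quantile normalization. The 281 calls became 131 without WT MDP replicate 1, 45 without WT MDP replicate 2, 82 without d56 MDP replicate 1 and 45 without d56 MDP replicate 2. The calls were 1456 with only the compared groups in the fit and 150 to 346 at other settings.

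In d56 cMoP, called genes of the MHC class I and interferon-stimulated lists were higher, beside a median over all genes of 0.149 (-0.003 with median-of-ratios scaling). Abca9, a lipid transporter, rose from 2.52 ± 2.27 to 27 ± 2.02 TPM (log2 fold change 3.16, SE 0.35, adjusted p = 4.2e-06), and Kctd14, a potassium channel domain gene, fell from 39.7 ± 16.3 to 4.39 ± 0.566 TPM (log2 fold change -2.86, SE 0.60, adjusted p = 0.00487). Rab38, a small GTPase, fell from 17.3 ± 0.679 to 3.52 ± 0.813 TPM (log2 fold change -2.03, SE 0.37, adjusted p = 0.00179). Of the MHC class I and peptide loading list, 5 of 14 tested genes rose and 0 fell (7 and 0 over the list alone), first H2-Q7 and Nlrc5, median 0.24, camera adjusted p = 0.00645 (0.384 with estimated correlation). In the basophil, mast cell and eosinophil list, 0 of 8 tested genes fell and 0 rose, median -0.83, camera adjusted p = 0.0102 (0.358 with estimated correlation). Within the interferon-stimulated list, 6 of 23 tested genes rose and 0 fell (8 and 0 over the list alone), first Rtp4 and Oasl2, median 0.58, camera adjusted p = 0.0136 (0.442 with estimated correlation). In all 608 genes were higher and 117 lower (7 and 4 near the TPM ceiling) of 10741 tested, and 6 of 28 lists were called, 0 with an estimated correlation (camera, 3 at unadjusted p under 0.05). The 6 called lists became 3 without WT cMoP replicate 1 and 2 without d56 cMoP replicate 2. The share of calls that were higher, 83.9%, became 44.7% with median-of-ratios scaling and 59.5% with quantile normalization. The 725 calls became 467 without WT cMoP replicate 1, 66 without WT cMoP replicate 2, 157 without d56 cMoP replicate 1 and 92 without d56 cMoP replicate 2. Called genes numbered 1855 with only the compared groups in the fit and 306 to 945 at other settings.

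In d56 Ly6C+Mo, the cell cycle list and called late neutrophil genes were higher and called MHC class II genes lower. Ngp, neutrophilic granule protein, was listed at 0 in both WT libraries and at 186 and 76.3 TPM in d56, and Zfp280c, a zinc finger gene, was listed at 0 in both d56 libraries and at 40.1 and 36.3 TPM in WT. Apbb1, an adaptor of amyloid precursor protein, was listed at 0 in both d56 libraries and at 28.8 and 37.3 TPM in WT. For the cell cycle list, 28 of 28 tested genes rose and 0 fell, first Bub1 and Ccne2, median 3.07, camera adjusted p = 7.77e-36 (5.19e-06 with estimated correlation). Of the WT Ly6C-Mo signature, 42 of 79 tested genes fell and 1 rose (43 and 1 over the list alone), first Pparg and Ms4a7, median -1.0, camera adjusted p = 2.55e-07 (0.0302 with estimated correlation). In the interferon-stimulated list, 17 of 28 tested genes fell and 0 rose (21 and 0 over the list alone), first Rsad2 and Ifit3, median -1.08, camera adjusted p = 1.15e-06 (0.258 with estimated correlation). Within the late neutrophil list, 9 of 19 tested genes rose and 0 fell, first Ngp and S100a9, median 2.89, camera adjusted p = 0.00288 (0.389 with estimated correlation). For the WT cDC2 signature, 13 of 35 tested genes fell and 4 rose (15 and 5 over the list alone), first Cd209d and Wnt11, median -0.84, camera adjusted p = 0.0396 (0.348 with estimated correlation). Of the MHC class II list, 9 of 10 tested genes fell and 0 rose, first Ciita and Cd74, median -1.42, camera adjusted p = 0.00034 (0.258 with estimated correlation). The WT cDC2 signature shares 6 genes with the pDC list and 0 with the cDC2 list. The d56 replicates differed in granulocyte genes, with S100a9 at 11134 and 1520.3 TPM. In all 2144 genes were higher and 2131 lower (12 and 83 near the TPM ceiling) of 10837 tested, and 14 of 30 lists were called, 2 with an estimated correlation. The 14 called lists became 8 without d56 Ly6C+Mo replicate 2. The calls were 1027 with only the compared groups in the fit and 3733 to 4560 at other settings.

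**Figure D2:**
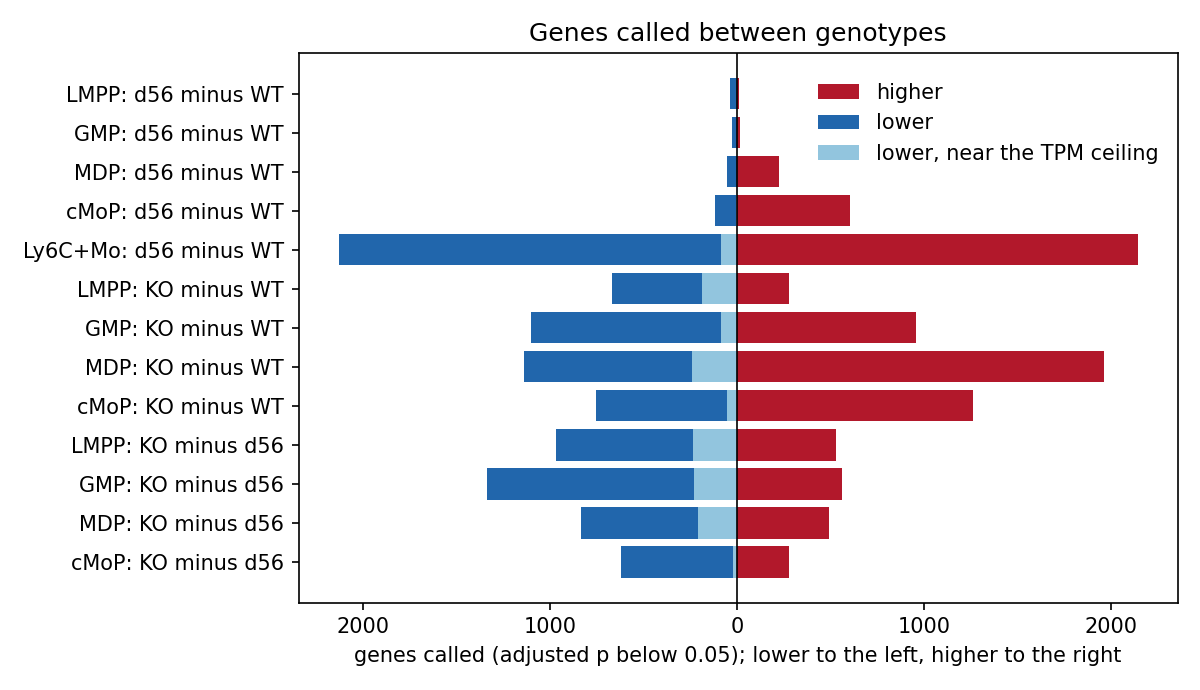
Number of genes called in each genotype comparison at adjusted p below 0.05, with higher calls to the right, lower calls to the left and the lower calls near the TPM ceiling in light blue. The bars of d56 Ly6C+Mo reach 2144 higher and 2131 lower, against 9 and 39 in d56 LMPP.

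KO and WT cells were compared next. In KO LMPP, called genes of the late neutrophil list were higher and those of the tissue macrophage and cDC1 lists lower. Chil3, a chitinase-like protein, rose from 1.2 ± 0.247 to 58.4 ± 6.69 TPM (log2 fold change 4.76, SE 1.02, adjusted p = 0.00487), and Hba-a1, alpha globin, was listed at 0 in both KO libraries and at 231 and 35.3 TPM in WT. Hba-a2, its near-identical copy, with which reads may be shared, was listed at 0 in both KO libraries and at 224 and 30.7 TPM in WT. In the tissue macrophage list, 7 of 9 tested genes fell and 0 rose (8 and 0 over the list alone), first Hmox1 and C1qb, median -2.58, camera adjusted p = 1.16e-13 (8.17e-05 with estimated correlation). Within the cDC1 list, 9 of 16 tested genes fell and 0 rose (11 and 0 over the list alone), first Cadm1 and Naaa, median -1.39, camera adjusted p = 3.3e-12 (0.008 with estimated correlation). For the late neutrophil list, 7 of 21 tested genes rose and 0 fell (11 and 0 over the list alone), first Chil3 and Lcn2, median 2.59, camera adjusted p = 9.22e-09 (0.115 with estimated correlation). Of the immediate early list, 8 of 15 tested genes fell and 0 rose (9 and 1 over the list alone), first Hspa1b and Hspa1a, median -0.47, camera adjusted p = 6.87e-06 (0.0165 with estimated correlation). Handling can induce genes of this list. In the WT cDC1 signature, 9 of 42 tested genes fell and 1 rose (9 and 2 over the list alone), first Cadm1 and Naaa, median -0.34, camera adjusted p = 0.000475 (0.149 with estimated correlation). In all 279 genes were higher and 668 lower (0 and 184 near the TPM ceiling) of 11727 tested, and 18 of 30 lists were called, 3 with an estimated correlation. The 947 calls became 293 without WT LMPP replicate 1, 404 without WT LMPP replicate 2, 480 without KO LMPP replicate 1 and 341 without KO LMPP replicate 2. Called genes numbered 94 with only the compared groups in the fit and 656 to 1227 at other settings.

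In KO GMP, called genes of the neutrophil signature were higher and those of the stem cell and erythroid lists lower. Ltf, lactoferrin, rose from 0.835 ± 0.7 to 149 ± 5.47 TPM (log2 fold change 6.41, SE 1.56, adjusted p = 0.00551), and Car1, an erythroid carbonic anhydrase, was listed at 0 in both KO libraries and at 45.2 and 184 TPM in WT. Ly86, a partner of a Toll-like receptor, was listed at 0 in both KO libraries and at 60.3 and 67 TPM in WT. Within the WT LT-HSC signature, 44 of 79 tested genes fell and 0 rose (47 and 0 over the list alone), first Car1 and Pf4, median -1.21, camera adjusted p = 1.37e-20 (0.000281 with estimated correlation). For the WT Neu signature, 39 of 61 tested genes rose and 0 fell (42 and 3 over the list alone), first Chil4 and Chil1, median 1.62, camera adjusted p = 4.61e-19 (0.01 with estimated correlation). Of the erythroid list, 7 of 12 tested genes fell and 0 rose (11 and 0 over the list alone), first Car1 and Klf1, median -2.91, camera adjusted p = 6.84e-09 (0.00367 with estimated correlation). In the stem cell list, 5 of 9 tested genes fell and 0 rose (8 and 0 over the list alone), first Gata2 and Mpl, median -1.73, camera adjusted p = 9.42e-06 (0.00178 with estimated correlation). Within the MHC class II list, 8 of 10 tested genes fell and 0 rose, first Cd74 and H2-Aa, median -1.54, camera adjusted p = 2.71e-08 (0.0301 with estimated correlation). The WT LT-HSC signature shares 7 genes with the stem cell list, 5 with the megakaryocyte list and 4 with the erythroid list. In all 959 genes were higher and 1100 lower (5 and 85 near the TPM ceiling) of 10990 tested, and 11 of 29 lists were called, 9 with an estimated correlation. The 2059 calls became 692 without WT GMP replicate 2 and 844 without KO GMP replicate 1. The calls were 961 with only the compared groups in the fit and 1631 to 2335 at other settings.

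In KO MDP, called genes of the neutrophil signature were mostly higher, those of the monocyte list mostly lower and those of the MHC class II list lower. S100a9 rose from 20.9 ± 19.3 to 1758 ± 312 TPM (log2 fold change 6.67, SE 1.30, adjusted p = 0.000473), and Ly86 was listed at 0 in both KO libraries and at 145 and 149 TPM in WT. Klrk1, an NK cell receptor, was listed at 0 in both KO libraries and at 36.7 and 24.5 TPM in WT. For the WT Neu signature, 33 of 48 tested genes rose and 1 fell (36 and 1 over the list alone), first S100a9 and Prom1, median 1.76, camera adjusted p = 6.82e-08 (0.112 with estimated correlation). Of the monocyte list, 7 of 19 tested genes fell and 1 rose (8 and 2 over the list alone), first Ly86 and Klf4, median -0.4, camera adjusted p = 0.000133 (0.142 with estimated correlation). In the MHC class II list, 4 of 9 tested genes fell and 0 rose (6 and 0 over the list alone), first Cd74 and H2-Aa, median -0.65, camera adjusted p = 0.000133 (0.143 with estimated correlation). In all 1965 genes were higher and 1140 lower (8 and 240 near the TPM ceiling) of 10903 tested, and 10 of 27 lists were called, 0 with an estimated correlation (camera, 7 at unadjusted p under 0.05). Median-of-ratios scaling moved the share of higher calls from 63.3% to 43.2%, and quantile normalization moved it to 40.8%. The 3105 calls became 1269 without WT MDP replicate 2 and 1728 without KO MDP replicate 1.

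In KO cMoP, called genes of the neutrophil signature were mostly higher and those of the monocyte list mostly lower. S100a9 rose from 115 ± 2.06 to 3959 ± 92.1 TPM (log2 fold change 5.09, SE 1.30, adjusted p = 0.00639), and Ly86 fell from 136 ± 3.32 to 0.695 ± 0.983 TPM (log2 fold change -6.48, SE 0.54, adjusted p = 1.38e-09). Rasa4, a Ras GTPase-activating protein, fell from 200.3 ± 38.4 to 4.53 ± 1.04 TPM (log2 fold change -5.19, SE 0.19, adjusted p = 7.01e-17). Within the WT Neu signature, 32 of 50 tested genes rose and 1 fell (37 and 1 over the list alone), first S100a9 and Prom1, median 1.6, camera adjusted p = 8.26e-10 (0.116 with estimated correlation). For the monocyte list, 8 of 19 tested genes fell and 1 rose, first Ly86 and Ctss, median -0.14, camera adjusted p = 1.12e-06 (0.116 with estimated correlation). Of the late neutrophil list, 10 of 17 tested genes rose and 0 fell (11 and 0 over the list alone), first S100a9 and Cd177, median 1.69, camera adjusted p = 0.000129 (0.235 with estimated correlation). In the sex-linked list, 2 of 4 tested genes fell and 0 rose (3 and 0 over the list alone), first Eif2s3y and Ddx3y, median -1.91, camera adjusted p = 0.0444 (0.444 with estimated correlation). The median of that list became 0.57 without KO cMoP replicate 1, whose library lists Ddx3y at 0 against 24.7 TPM in replicate 2. In all 1263 genes were higher and 755 lower (10 and 54 near the TPM ceiling) of 10756 tested, and 10 of 28 lists were called, 0 with an estimated correlation (camera, 5 at unadjusted p under 0.05). Higher genes made up 62.6% of calls, 44.1% with median-of-ratios scaling and 44.6% with quantile normalization. The 2018 calls became 1321 without WT cMoP replicate 1, 991 without WT cMoP replicate 2 and 1112 without KO cMoP replicate 2.

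**Figure D3:**
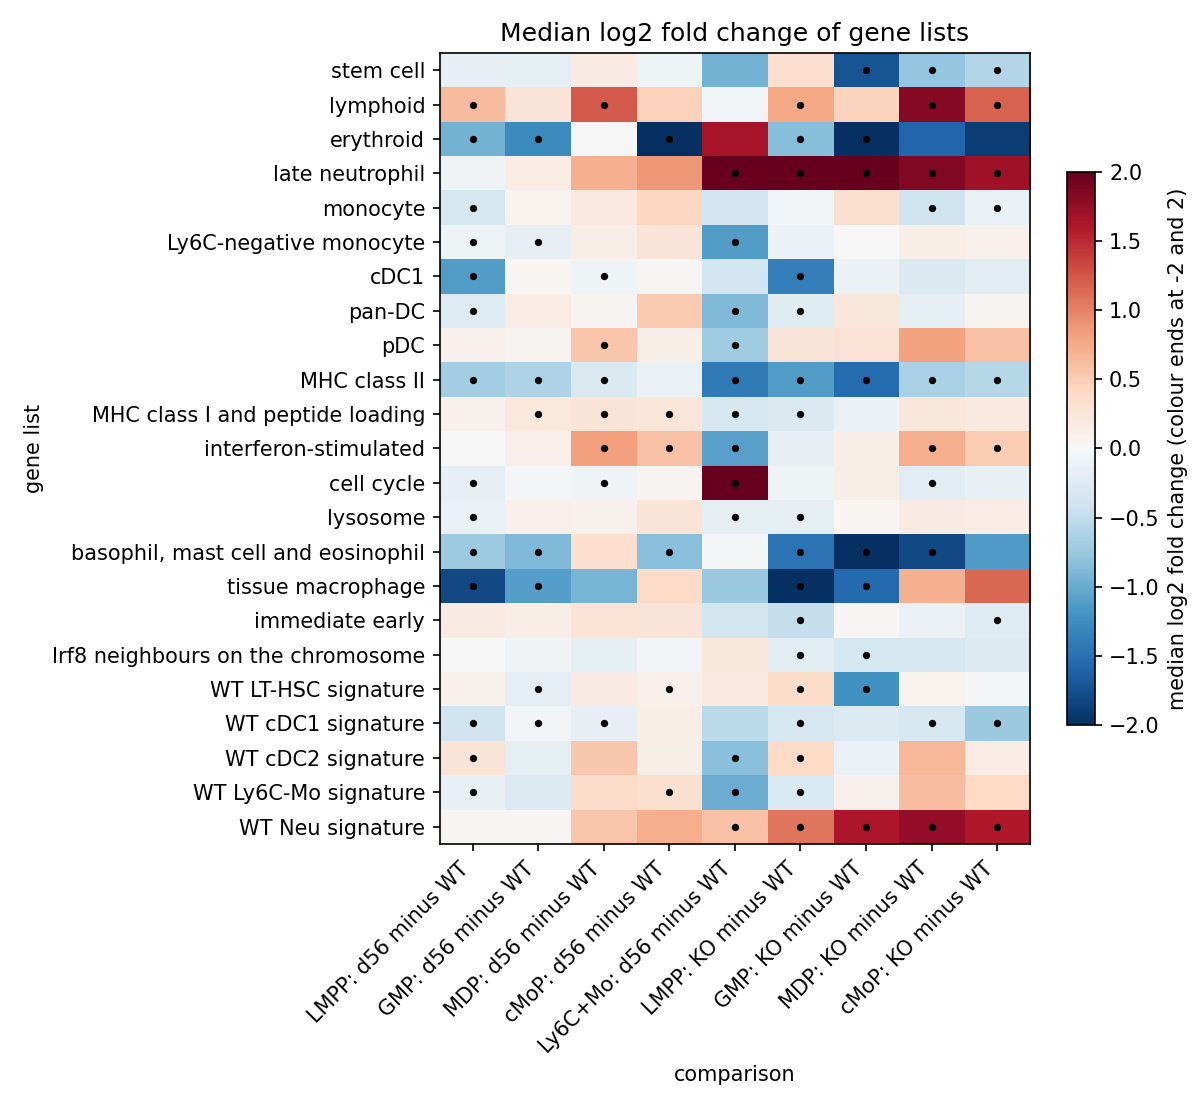
Median log2 fold change of gene lists called in 2 or more of the 9 comparisons with WT, the sex-linked list left out, with colour ends at -2 and 2 and a dot where camera gave adjusted p below 0.05 at the preset correlation. The MHC class II list runs from -0.29 in d56 MDP to -1.54 in KO GMP among the columns with a dot.

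KO and d56 cells were then compared directly. In LMPP, called genes of the late neutrophil list were higher in KO and those of the MHC class I list lower. S100a9 rose from 58.8 ± 71.8 to 1096 ± 78.7 TPM (log2 fold change 5.12, SE 1.30, adjusted p = 0.0094), and Hspa1b, a heat shock gene, fell from 108 ± 129 to 0.175 ± 0.0636 TPM (log2 fold change -5.69, SE 1.07, adjusted p = 0.000688). Hspa1a, its near-identical copy, fell from 96.7 ± 116 to 0.285 ± 0.0919 TPM (log2 fold change -5.37, SE 1.07, adjusted p = 0.00131). Within the late neutrophil list, 11 of 21 tested genes rose and 0 fell (15 and 0 over the list alone), first S100a9 and Chil3, median 3.14, camera adjusted p = 3.49e-08 (0.189 with estimated correlation). For the MHC class I and peptide loading list, 10 of 14 tested genes fell and 0 rose, first H2-Q7 and B2m, median -0.42, camera adjusted p = 1.53e-06 (0.189 with estimated correlation). In all 532 genes were higher and 970 lower (0 and 235 near the TPM ceiling) of 11666 tested, and 7 of 30 lists were called, 2 with an estimated correlation. The ceiling was 186 to 194 TPM in KO and 253 to 283 in d56, so MHC class I falls may follow from it. Calls were fewer without any 1 library. Called genes numbered 986 with only the compared groups in the fit and 1143 to 1865 at other settings.

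In GMP, called genes of the neutrophil signature were higher in KO than in d56 and those of the stem cell list lower. Ltf rose from 0.035 ± 0.0495 to 149 ± 5.47 TPM (log2 fold change 7.18, SE 1.56, adjusted p = 0.00202), and Pf4, platelet factor, was listed at 0 in both KO libraries and at 91.8 and 72.9 TPM in d56. Car1 was listed at 0 in both KO libraries and at 38.3 and 39.4 TPM in d56. Of the WT Neu signature, 30 of 61 tested genes rose and 0 fell (33 and 0 over the list alone), first Chil1 and Cd177, median 1.27, camera adjusted p = 1.34e-22 (0.00722 with estimated correlation). In the WT LT-HSC signature, 35 of 73 tested genes fell and 0 rose (43 and 0 over the list alone), first Pf4 and Car1, median -1.01, camera adjusted p = 7.85e-14 (0.00663 with estimated correlation). Within the stem cell list, 3 of 8 tested genes fell and 0 rose (5 and 0 over the list alone), first Mpl and Gata2, median -1.39, camera adjusted p = 0.000262 (0.0184 with estimated correlation). In all 563 genes were higher and 1337 lower (3 and 230 near the TPM ceiling) of 10934 tested, and 11 of 28 lists were called, 4 with an estimated correlation. The share of calls that were higher, 29.6%, became 43.2% with median-of-ratios scaling and 39.1% with quantile normalization. The 1900 calls became 697 without d56 GMP replicate 1, 1133 without d56 GMP replicate 2 and 827 without KO GMP replicate 1.

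In MDP, called genes of the neutrophil signature were higher in KO than in d56 and those of the monocyte list lower. S100a9 rose from 58.8 ± 28.7 to 1758 ± 312 TPM (log2 fold change 4.96, SE 1.30, adjusted p = 0.0131), and Ly86 was listed at 0 in both KO libraries and at 116 and 122 TPM in d56. Prg2, eosinophil major basic protein, was listed at 0 in both KO libraries and at 50.2 and 43 TPM in d56. For the WT Neu signature, 14 of 51 tested genes rose and 0 fell (28 and 1 over the list alone), first S100a9 and Chil4, median 1.16, camera adjusted p = 8.15e-10 (0.0853 with estimated correlation). Of the monocyte list, 7 of 19 tested genes fell and 0 rose (8 and 0 over the list alone), first Ly86 and Klf4, median -0.45, camera adjusted p = 1.46e-06 (0.0853 with estimated correlation). In all 493 genes were higher and 832 lower (2 and 207 near the TPM ceiling) of 10956 tested, and 8 of 29 lists were called, 0 with an estimated correlation (camera, 7 at unadjusted p under 0.05). The 1325 calls became 405 without d56 MDP replicate 1, 410 without d56 MDP replicate 2, 559 without KO MDP replicate 1 and 646 without KO MDP replicate 2.

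In cMoP, called genes of the monocyte list were lower in KO than in d56. Gjb3, a connexin, rose from 1.04 ± 0.905 to 23.8 ± 5.71 TPM (log2 fold change 3.66, SE 0.58, adjusted p = 0.000125), and Ly86 fell from 114 ± 5.06 to 0.695 ± 0.983 TPM (log2 fold change -6.21, SE 0.54, adjusted p = 7.23e-09). Klf4, a transcription factor required for Ly6C+ monocytes, fell from 27 ± 1.58 to 0.09 ± 0.127 TPM (log2 fold change -4.69, SE 0.26, adjusted p = 8.44e-13). In the monocyte list, 9 of 19 tested genes fell and 0 rose (10 and 0 over the list alone), first Ly86 and Klf4, median -0.78, camera adjusted p = 9.03e-13 (0.0123 with estimated correlation). Within the WT Neu signature, 12 of 51 tested genes rose and 1 fell (21 and 1 over the list alone), first Slc40a1 and Lilr4b, median 1.14, camera adjusted p = 2.17e-11 (0.0598 with estimated correlation). In all 280 genes were higher and 620 lower (3 and 22 near the TPM ceiling) of 10771 tested, and 10 of 27 lists were called, 1 with an estimated correlation. Median-of-ratios scaling moved the share of higher calls from 31.1% to 43.1%, and quantile normalization moved it to 38.7%. The 900 calls became 305 without d56 cMoP replicate 1, 431 without d56 cMoP replicate 2 and 428 without KO cMoP replicate 1.

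Genes that changed against WT overlapped between the mutants, which share their 2 WT libraries per population. In LMPP, 6 genes were higher and 29 lower in both, against 0.1 and 2.3 for independent lists of those sizes. In GMP, 12 were higher and 18 lower in both, against 1.5 and 2.8. In MDP, 198 were higher and 48 lower, against 39.2 and 5.6, and in cMoP 366 were higher and 78 lower, against 68.6 and 8.3. Calls in opposite directions numbered 0 in LMPP, 3 in GMP, 1 in MDP and 2 in cMoP. Fold changes correlated across genes at r = 0.40 in LMPP, 0.54 in GMP, 0.69 in MDP and 0.63 in cMoP, against simulated values of 0.50, 0.50, 0.51 and 0.50. With 1 WT library as the control of d56 and the other as that of KO, a test added after the data were seen, unchanged groups would give r near 0. The r was 0.13 and 0.10 in LMPP for the 2 ways to assign them, 0.28 and 0.37 in GMP, 0.56 and 0.55 in MDP and 0.57 and 0.44 in cMoP. The overlaps for these assignments were 2 higher and 7 lower or 5 and 5 in LMPP, 2 and 11 or 11 and 7 in GMP, 29 and 10 or 84 and 11 in MDP and 46 and 7 or 144 and 19 in cMoP, and independent lists would give at most 0.5, 1.1, 8.9 and 21.2 in either direction. Opposite calls numbered 0 or 1 in LMPP, 4 or 0 in GMP, 0 in both for MDP and 0 or 5 in cMoP. A deviation that both WT libraries share is not removed by this.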

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

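The tests of a lower KO ceiling over all lower genes and of a length and GC trend were set down before their results were seen, and all other tests of explanations here were chosen after. Genotype effects differed between neighbouring populations by a limma test of the difference, and the genes named, those with the largest differences, were chosen after their values were seen. The d56 effect differed between GMP and LMPP in 5 genes, first Naaa (3.36, adjusted p = 0.0017) and Stx11 (2.49, adjusted p = 0.000403), on the log2 scale. Without WT LMPP replicate 1, Naaa was 2.65 with adjusted p = 0.0212 and Stx11 2.19 with adjusted p = 0.0089. The 5 calls became 12 without WT LMPP replicate 2, 3 without WT GMP replicate 1 and 3 without WT GMP replicate 2. Limma called 0, with 590 at unadjusted p under 0.05, with only the compared groups in the fit and 2 to 10 at other settings. Between MDP and GMP it differed in 6 genes, first Rtp4 (3.16, adjusted p = 3.23e-05). The 6 calls became 1 to 3 without any 1 of the libraries other than d56 GMP replicate 2, and were 7 with only the compared groups in the fit and 3 to 11 at other settings. Between cMoP and MDP limma called 0, with 281 at unadjusted p under 0.05. The 0 calls became 1 without d56 cMoP replicate 1. It called 20 with only the compared groups in the fit and 0 to 5 at other settings. Between spleen Ly6C+Mo and bone marrow cMoP it differed in 3408 genes, first Gtse1 (6.19, adjusted p = 1.83e-11) and P2ry14 (-5.92, adjusted p = 0.00037). The calls were 1807 with only the compared groups in the fit and 2894 to 3530 at other settings.

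The KO effect differed between GMP and LMPP in 346 genes, first Gfi1b (-5.94, adjusted p = 4.35e-05), Pf4 (-5.79, adjusted p = 2.41e-05) and Slc14a1 (-5.63, adjusted p = 0.000578). The 346 calls became 199 without WT LMPP replicate 1, 219 without WT GMP replicate 2 and 227 without KO GMP replicate 1. They were 124 with only the compared groups in the fit and 172 to 515 at other settings. Between MDP and GMP it differed in 212 genes, first Olfm1 (-5.81, adjusted p = 0.00687), which was -5.34 with adjusted p = 0.0561 without WT GMP replicate 1. The 212 calls became 99 without WT GMP replicate 1, 133 without WT MDP replicate 1, 115 without WT MDP replicate 2 and 141 without KO GMP replicate 2. They were 172 with only the compared groups in the fit and 128 to 279 at other settings. Between cMoP and MDP it differed in 12 genes, and in 1 with only the compared groups in the fit and 8 to 14 at other settings. The 12 calls became 5 without WT MDP replicate 1, 5 without WT MDP replicate 2, 7 without WT cMoP replicate 1, 7 without KO MDP replicate 2 and 33 without KO cMoP replicate 2.

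TPM of genes with 1 curated RefSeq transcript stayed under a ceiling, with a high percentile of 162 to 283 TPM per library against 2253 to 3977 TPM for genes with more. A candidate explanation is removal of duplicate reads where an alignment is unique to 1 transcript. Ribosomal protein genes with more than 1 transcript had 9.46 times the median TPM of those with 1, but the lower quartile of the former was 177.3 TPM and the upper quartile of the latter 184.7 TPM, so lower expression of such genes stays open. Whether the submitters removed duplicates is not stated.

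In all 4 KO populations 181 genes were called in the same direction, 54 higher and 127 lower. A length and GC trend as the whole cause is argued against, as 58.6% were still called in all 4 after its correction. The 22 histone genes were picked as lower, so the cell cycle list lying 1.14 above them (log2) cannot test fewer cycling cells. That list had a mean median of -0.08. A lower ceiling may account for some falls. Near it were 25.2% of lower genes and 0 of 54 higher, against 3% of genes tested in GMP. For histone genes 0.0% were, but symbols without a RefSeq match cannot be, so it stays open. Loss of IRF8 and a shift of all KO libraries cannot be told apart, as the labels name no batch and every KO library has 1 genotype. With 1 WT library of each population as the control of KO and the other as that of d56, 82% of 50 and 68.4% of 19 genes called in all 4 had the same sign in d56, for the 2 ways to assign them. By the shares of all genes above and below 0 in d56, 45.7% and 39.1% would. The same sign was held by 17 of 18 higher and 24 of 32 lower genes, and by 4 of 4 and 9 of 15.

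Called genes of the cDC1 list were lower in mutant than in WT LMPP. Cells of the cDC1 lineage in the WT gate may contribute, since of the WT cDC1 signature genes that are not on the cDC1 list, 82.9% were higher in WT LMPP replicate 1 than in replicate 2, against 51.2% to 63.8% in the other signatures. Replicate 1 had been picked for its Xcr1, a cDC1 list gene. The median difference to replicate 2 was 0.3 times that to replicate 1, and lower expression per cell stays open.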

How the results depend on the processing

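Length and GC correction and leaving out genes near the ceiling were chosen after the data were seen. Each group had 2 libraries and the depth is unknown, so leaving out 1 library left a lone sample that was assumed to vary like the other groups. The cause of the changes below was not tested, except that leaving out a library or fitting only the compared groups leaves fewer residual degrees of freedom.

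Of values for single genes other than Irf8 under the alternatives chosen before the data were examined, leave-one-out aside, 2475 kept their direction and call and 133 lost the call. For lists these numbers were 2282 and 400, with 1 reversed. Leaving out a library kept 1051 gene values and 1075 list values and ended the call of 253 and 118, with 3 list values reversed. Irf8, not in these numbers, changed sign in 5 values on leaving out a library and in 1 after length and GC correction. The alternatives added later kept 635 gene and 564 list values and ended the call of 7 and 34.

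With the replicate block, in case equal replicate numbers are paired, called genes were 50 in LMPP d56 against WT, 41 in GMP d56 against WT and 928 in LMPP KO against WT. Residuals of equal numbers correlated at 0.13 to 0.34 among WT LMPP, GMP, MDP, CDP and cMoP, and among LMPP, GMP, MDP and cMoP at 0.10 to 0.22 in d56 and -0.10 to 0.08 in KO. Between WT LT-HSC, ST-HSC, MPP2 or MPP3 and those 5 WT groups r was -0.11 to 0.03, between d56 Ly6C+Mo and the other d56 groups -0.06 to -0.01, and between mutant and WT of 1 population -0.18 to 0.16.

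Values that moved are given by setting, those of Irf8 as log2 fold changes where its call or sign changed, with a difference of effects named as an effect. Fitting only the compared groups leaves fold changes as they were. Pseudocount 0.1: Called genes became 25 in LMPP d56 against WT, 27 in GMP d56 against WT, 183 in MDP d56 against WT, 3 in d56 effect GMP against LMPP, 172 in KO effect GMP against LMPP and 128 in KO effect MDP against GMP. The Irf8 call was lost in CDP against MDP (1.051). Pseudocount 5: Called genes became 74 in LMPP d56 against WT, 10 in d56 effect GMP against LMPP, 11 in d56 effect MDP against GMP and 5 in d56 effect cMoP against MDP. Irf8 was called in Ly6C-Mo against Ly6C+Mo (-0.985) and MDP KO against WT (-0.927). No filter on mean TPM: Called genes became 8 in d56 effect GMP against LMPP. Called lists became 7 in cMoP against MDP and 6 in cMoP KO against WT. Mean TPM of 5 or more: Called genes became 19 in LMPP d56 against WT, 28 in GMP d56 against WT, 2 in d56 effect GMP against LMPP, 213 in KO effect GMP against LMPP and 130 in KO effect MDP against GMP. Called lists became 7 in cMoP against MDP, 3 in cMoP d56 against WT and 6 in cMoP KO against d56. The camera direction of the erythroid list in cMoP against MDP changed from lower, with a median of 0.273, to higher, with 0.9. Median-of-ratios scaling: Called genes became 3 in d56 effect MDP against GMP. Called lists became 3 in cMoP d56 against WT and 6 in cMoP KO against d56. Irf8 was called in Ly6C-Mo against Ly6C+Mo (-1.07) and MDP KO against WT (-1.071). Quantile normalization: Called genes became 150 in MDP d56 against WT, 306 in cMoP d56 against WT and 1 in d56 effect cMoP against MDP. Called lists became 11 in cMoP d56 against WT. The Irf8 call was lost in MDP d56 against WT (-1.509). Only the compared groups: Called genes became 17 in cMoP against MDP, 1 in LMPP d56 against WT, 5 in GMP d56 against WT, 1456 in MDP d56 against WT, 1855 in cMoP d56 against WT, 1027 in Ly6C+Mo d56 against WT, 94 in LMPP KO against WT, 961 in GMP KO against WT, 986 in LMPP KO against d56, 0 in d56 effect GMP against LMPP, 20 in d56 effect cMoP against MDP, 1807 in d56 effect Ly6C+Mo against cMoP, 124 in KO effect GMP against LMPP and 1 in KO effect cMoP against MDP. Called lists became 6 in cMoP KO against WT and 6 in cMoP KO against d56. The Irf8 call was lost in LMPP d56 against WT (-2.257). Irf8 was called in cDC1 against CDP (0.734), Ly6C+Mo against cMoP (-0.398), Ly6C-Mo against Ly6C+Mo (-0.994), cMoP d56 against WT (-0.995), GMP KO against WT (-0.567), MDP KO against WT (-0.932), MDP KO against d56 (0.709) and d56 effect MDP against GMP (1.26). Length and GC correction: Called genes became 345 in cMoP d56 against WT. Irf8 was called in Ly6C-Mo against Ly6C+Mo (-1.171) and MDP KO against WT (-1.099). Irf8 changed sign in GMP against LMPP (0.059). Without genes near the ceiling: Called lists became 6 in cMoP KO against d56. Estimated inter-gene correlation: Called lists became 6 in LMPP against LT-HSC, 6 in GMP against LMPP, 5 in MDP against GMP, 2 in CDP against MDP, 3 in cMoP against MDP, 3 in CDP against cMoP, 8 in cDC1 against CDP, 6 in cDC2 against CDP, 2 in cDC1 against cDC2, 9 in Ly6C+Mo against cMoP, 4 in Neu against GMP, 4 in LMPP d56 against WT, 5 in GMP d56 against WT, 1 in MDP d56 against WT, 0 in cMoP d56 against WT, 2 in Ly6C+Mo d56 against WT, 3 in LMPP KO against WT, 0 in MDP KO against WT, 0 in cMoP KO against WT, 2 in LMPP KO against d56, 4 in GMP KO against d56, 0 in MDP KO against d56 and 1 in cMoP KO against d56.

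Leaving out each library in turn gave these ranges of called genes: 2891 to 4156 in GMP against LMPP, 24 to 48 in LMPP d56 against WT, 293 to 480 in LMPP KO against WT, 3 to 12 in d56 effect GMP against LMPP, 199 to 304 in KO effect GMP against LMPP, 577 to 984 in MDP against GMP, 13 to 38 in GMP d56 against WT, 692 to 1627 in GMP KO against WT, 1 to 6 in d56 effect MDP against GMP, 99 to 228 in KO effect MDP against GMP, 2743 to 3576 in CDP against MDP, 2 to 6 in cMoP against MDP, 45 to 131 in MDP d56 against WT, 1269 to 2185 in MDP KO against WT, 0 to 1 in d56 effect cMoP against MDP, 5 to 33 in KO effect cMoP against MDP, 2712 to 3422 in CDP against cMoP, 66 to 467 in cMoP d56 against WT, 991 to 1518 in cMoP KO against WT, 1916 to 2353 in Ly6C-Mo against Ly6C+Mo, 694 to 917 in LMPP KO against d56, 697 to 1552 in GMP KO against d56, 405 to 646 in MDP KO against d56 and 305 to 648 in cMoP KO against d56. Called lists ranged from 6 to 10 in cMoP against MDP, 2 to 9 in cMoP d56 against WT and 8 to 16 in Ly6C+Mo d56 against WT. The Irf8 log2 fold change ranged from -0.853 to 0.207 in GMP against LMPP, -2.787 to -1.726 in LMPP d56 against WT, -0.65 to 0.41 in LMPP KO against WT, -0.978 to 0.083 in KO effect GMP against LMPP, 0.837 to 1.263 in CDP against MDP, -0.333 to 0.093 in cMoP against MDP, -1.854 to -1.428 in MDP d56 against WT and 1.022 to 1.318 in CDP against cMoP. List medians ranged from -0.616 to 0.268 for basophil, mast cell and eosinophil in cMoP against MDP, and for the sex-linked list from -4.383 to 0.57 in cMoP KO against WT and from -4.941 to 0.165 in cMoP KO against d56, reversed without WT cMoP replicate 2 and KO cMoP replicate 1.

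The median log2 fold change of all genes moved with scaling, as from 0.125 to -0.012 (median-of-ratios) and -0.016 (quantile) in d56 MDP, from 0.149 to -0.003 and -0.015 in d56 cMoP, from 0.150 to 0.019 and -0.037 in KO MDP, from -0.238 to -0.035 and 0.027 in GMP against LMPP and from -0.819 to -0.055 and -0.101 in Neu against GMP. Of the 99 list tests called between genotypes and WT, 84 were called with median-of-ratios scaling and 88 with quantile normalization, and 1 list median changed sign in each.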

Other observations

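These values, chosen after the data were seen, tested no hypothesis. ST-HSC, MPP2 and MPP3 entered no comparison. Mpo (myeloperoxidase) was 66.3 and 25.4 TPM in ST-HSC, 115 and 141 in MPP2 and 175 and 183 in MPP3. The ceiling was 162 and 168 TPM in MPP2 and 173 and 170 in MPP3. Its effect on Mpo was not tested. Cd34 was 670.3 and 759 TPM in ST-HSC, 213 and 224 in MPP2 and 869.7 and 933 in MPP3. Values are of replicates 1 and 2.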
